A study of Homo sapiens with 6 samples.

How the data were processed

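Chromatin contacts were measured by Hi-C with the Arima-HiC+ kit in 6 libraries of KOLF2.1J, an established human induced pluripotent stem cell (iPSC) line that carries a doxycycline-inducible transcription factor cassette in the CLYBL locus, per the labels. The cassette turns the stem cells (iTF-iPSCs) into microglia-like cells (iTF-Microglia). The groups were untreated iTF-iPSCs with 2 libraries, untreated iTF-Microglia at day 18 with 2 libraries, and iTF-Microglia at day 18 with 2 libraries given lipopolysaccharide (LPS, 100 ng/ml) and interferon gamma (IFNG, 20 ng/ml) for 24 h. The titles of the stimulated libraries give the LPS dose in mg/ml and the other labels in ng/ml, which is the unit used here. The labels do not say whether the libraries of a group came from separate cultures.

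The measurements used here were a single loop list for the whole series, written by juicer_tools 2.13.06 per the file headers, on the hg38 genome per the submitters' processing notes. Those notes also name BWA, cutadapt, Bowtie2, Picard, SAMtools and Juicer; their versions, the role of each and the mapping quality minimum are not given in the sources used here. For each loop the list gives 2 anchors of equal width and the count of contacts observed in the strongest pixel as the authors deposited it, a whole number with no normalization stated. It also gives 4 expected contact counts made by the authors' loop caller from the pixels around the loop (a donut, the lower left corner, a horizontal and a vertical strip), which are estimated counts and not whole numbers. The false discovery rates in the deposited list are q-values of the observed count against each of the 4 expected counts, and the highest among the loops used was 0.0994. Other deposited columns hold the number of neighbouring pixels merged into the loop (a count), the position of their centre and their radius, scores in base pairs by the authors' caller.

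The list has no column per library or per group, and which libraries were pooled into it is not given in the sources used here. Contacts of iTF-iPSCs, untreated and stimulated iTF-Microglia therefore could not be set against each other, and the planned comparison between groups was not run. Every value below describes one pooled list, so it has no replicate error and no p-value refers to a difference between groups. The depth per library is unknown. The observed count of each loop sets its precision, and the 95% intervals of single loops are exact Poisson intervals of that count divided by the donut expected count; they cover counting error only.

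Loops on chromosomes 1 to 22 and X were used, 26291 of the 26374 in the list. Loop length was taken as the distance between the starts of the anchors, and contact enrichment as the observed count divided by the donut expected count. Coordinates are printed from 1 on hg38. Genes were the 19974 protein-coding genes on the same chromosomes in the RefSeq table of assembly GRCh38.p14, the same genome build. That table gives the interval of each gene without its strand, so the plan to use the 5' end of each gene was replaced: a gene was placed at an anchor when either end of its interval lay inside the anchor, which mixes promoters with gene ends. The orientation of CTCF motifs, which needs the genome sequence, was not analysed here.

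The share of loops with gene ends at their anchors was set against 1000 random placements of the same loops, each on its own chromosome with its length and anchor width, within 1 Mb windows that hold an anchor of the list. Of 21 gene lists fixed before the data were examined, each was tested with a two-sided Fisher's exact test against all protein-coding genes, with Benjamini-Hochberg adjustment over the lists. Another 6 comparisons, not among the planned tests, set lists against each other with the same test, adjusted over the 6. That of the cassette, microglia and myeloid lists together against the pluripotency list was chosen after the results were seen. The Fisher test takes genes as independent, which neighbouring genes of a cluster are not. Contact enrichment of the loops of a list was compared with that of the other loops with a gene end at an anchor by a two-sided permutation test of the list's median with 100000 resamples, again adjusted over the lists, and loop length was related to contact enrichment by Spearman's rho with 100000 permutations. Loops are not independent replicates in these tests. The list of the cassette's 6 factors came from background knowledge, since the labels do not name them.

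Named genes followed a rule fixed before the data were examined: the 34 genes of a fixed key list whatever their result, up to 4 members of each list at an anchor with the highest contact enrichment, and the protein-coding genes at an anchor of the 10 loops with the highest enrichment, of the 5 longest loops and of the 5 anchors with the most loops. Results for some genes that the rule takes are not reported here, and genes outside it are said to be chosen after their values were seen.

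Alternatives fixed beforehand used 5 kb anchors alone, wider anchors alone, loops with a ratio of at least 2, loops of at least 3 pixels, chromosomes 1 to 22, loops and genes outside the major histocompatibility complex (MHC, chromosome 6, 25 to 34 Mb), the lowest ratio over the 4 expected counts, gene ends within 5 kb of an anchor, gene sets matched on the number of gene starts within 500 kb, random loop placements in place of random genes, permutation within anchor widths (and length quartiles for the lists), loops shifted by 200 kb, and anchors within 10 kb merged. Chosen after seeing the data were genes with any part in an anchor, loops of at most 5 Mb, and list members within 500 kb of each other counted once. In simulated data for the gene list test, over 19974 genes, 99% of lists of 40 genes with 50% of members moved onto anchors were called and 3% of random lists were. For the loop enrichment test, over 8000 loops, 100% of lists of 40 loops raised 1.5-fold were called and 2.5% of unchanged lists were. Both simulations called lists of random members at an unadjusted p under 0.05, in 100 runs for genes and 40 for loops. They do not cover the adjustment over lists, clustered members, shorter lists or smaller effects, so they do not give the power of the real tests there. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.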

Results

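Hi-C contacts were collected from KOLF2.1J iTF-iPSCs and from iTF-Microglia at day 18, untreated or given LPS and IFNG for 24 h, with 2 libraries in each of the 3 groups and 6 in all. The values described here come from a single pooled loop list, in which no contact is assigned to a library or a group. The 26291 loops on chromosomes 1 to 22 and X rested on 2538669 observed contacts in their strongest pixels, with a median of 76 contacts per loop and 5th and 95th percentiles of 31 and 221.

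Most loops were shorter than 1 Mb and showed about 3 times the contacts of their surroundings. The median loop length was 300 kb, with quartiles of 140 and 590 kb, and 95% of loops had a length up to 1425 kb. The median contact enrichment, observed over donut-expected contacts, was 2.90, with quartiles of 2.37 and 3.76. Anchors were 5 kb wide in 15005 loops, 10 kb in 7526 and 25 kb in 3760. The median length was 200, 385 and 775 kb at these widths, and the median enrichment was 3.42, 2.57 and 2.26. Enrichment rose with length weakly across all loops, with a Spearman's rho of 0.107 (permutation p = 1.00e-05, the smallest the resamples can give) and more clearly when loops were ranked within each anchor width, with a rho of 0.481. The pooled medians were flat from 0.1 to 2 Mb (2.95, 2.99, 2.95 and 2.95), with 2.59 for shorter loops and 3.18 for those of 2 to 5 Mb. A caller that tests counts also needs a higher ratio where fewer contacts are expected. The 131 calls over 5 Mb stood apart with a median enrichment of 11.5 on a median of 25 observed contacts, against 2.90 on 77 contacts for the loops up to 5 Mb.

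**Figure D1:**
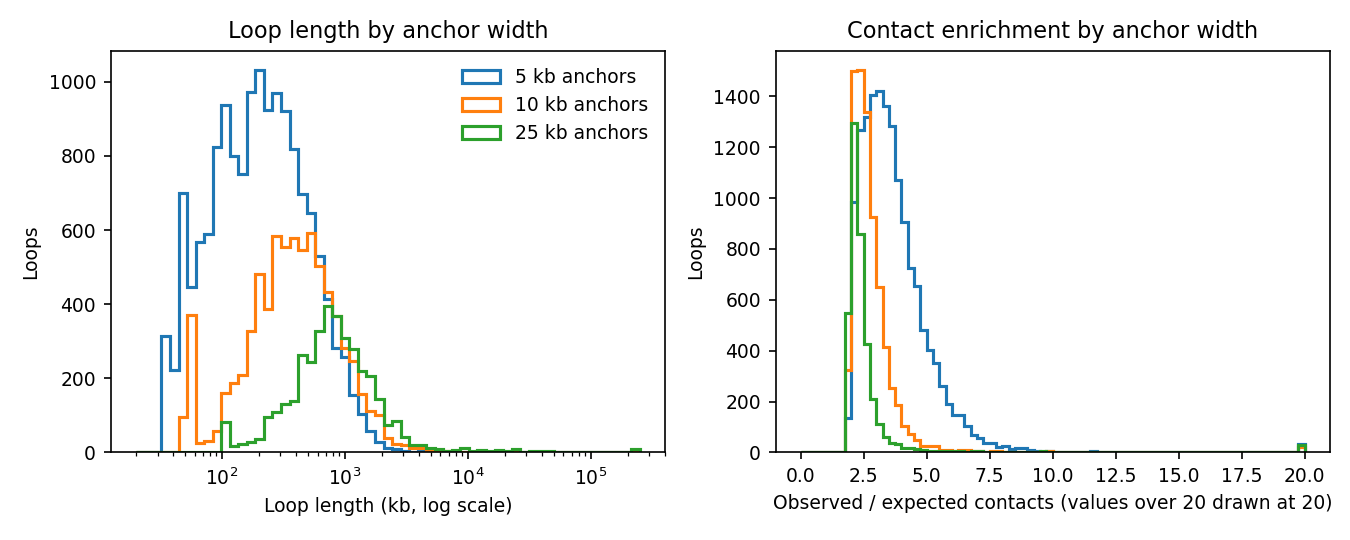
The left panel plots the number of loops by loop length in kb on a log scale, and the right panel by observed over expected contacts, with values over 20 drawn at 20; each line is an anchor width. Loops with 5 kb anchors had the lowest median length, 200 kb, and the highest median enrichment, 3.42.

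Loop anchors carried the ends of protein-coding genes more often than randomly placed loops did. Of all loops, 8449 (32.1%) had a gene end in at least 1 anchor, against a mean of 17.7% ± 0.229 (SD over 1000 placements), which is 1.81 times as many. Gene ends at both anchors were found in 1414 loops (5.38%), against 2.05% ± 0.0853 by placement, a ratio of 2.62. No placement reached either value (two-sided permutation p = 0.00200, one-sided p = 9.99e-04, the smallest that 1000 placements can give). In all, 7046 of the 19974 protein-coding genes (35.3%) had an end in an anchor. Loops without a gene end had a median enrichment of 3.02, those with a gene end at 1 anchor 2.75, and those with gene ends at both anchors 2.52, a decline with a Spearman's rho of -0.134 (permutation p = 1.00e-05). Within anchor widths rho was -0.0582, and at 25 kb the order of the medians turned, with 2.23, 2.28 and 2.31. When any part of the gene counted, a choice made after seeing the data, the excess over placement shrank to 1.12 for at least 1 anchor and to 1.09 for both.

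Developmental transcription factors and regulators of the myeloid lineage were found at loop anchors far more often than other genes, and olfactory receptors less often. Of 67 transcription factors of embryonic patterning, 55 had an end in an anchor (82.1%, odds ratio 8.47, 95% interval 4.48 to 17.4, Fisher's exact adjusted p = 4.47e-14). Of 35 myeloid regulators, 24 did (68.6%, odds ratio 4.01, interval 1.89 to 9.08, Fisher's exact adjusted p = 4.80e-04). With 5 kb anchors alone these odds ratios were 3.80 and 2.60, and with loops of at least 3 pixels that of the developmental factors was 4.73, all still passing. In total 10 of the 21 lists passed the Fisher's exact test at an adjusted p of 0.05, 7 with more genes at anchors than other genes and 3 with fewer, and the same number, 10, had an unadjusted p under 0.05.

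**Figure D2:**
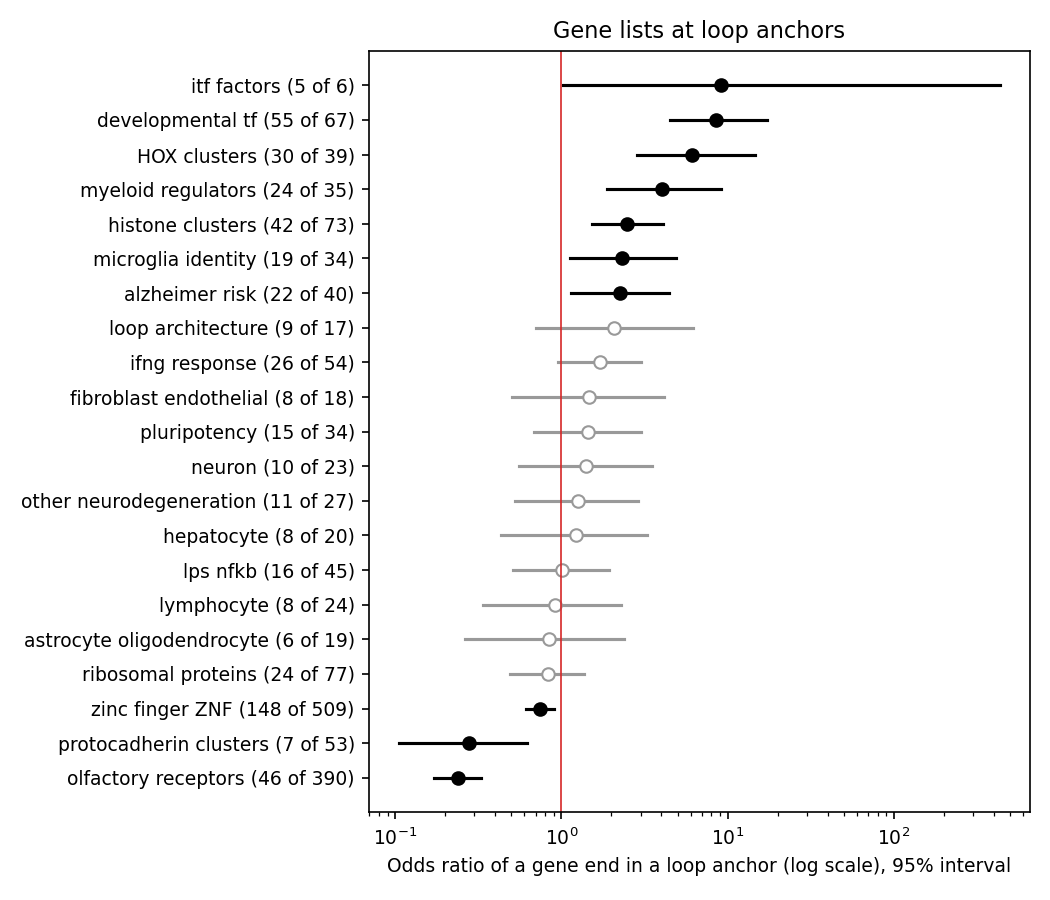
Odds ratio of having a gene end in a loop anchor for each of the 21 gene lists on a log scale, with its 95% interval and, in parentheses, the genes at an anchor and the genes in the list; filled black points passed an adjusted p of 0.05 and the vertical line marks an odds ratio of 1. The cassette factors have the highest estimate, 9.18, with the widest interval, 1.03 to 434, and the olfactory receptors the lowest, 0.240.

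The factors of the microglia-inducing cassette were at an anchor at their own loci in 5 of 6 cases (odds ratio 9.18, interval 1.03 to 434, Fisher's exact adjusted p = 0.0486). SPI1 encodes PU.1, the master regulator of myeloid cells. SPI1 had 1 loop of 175 kb on chromosome 11, at an enrichment of 3.93 (interval 3.03 to 5.02). The loop ran from an anchor that also holds an end of MYBPC3 to an anchor with the ends of ARFGAP2 and PACSIN3. Strand was not given, so a gene end at an anchor may be the 5' or the 3' end. This holds for SPI1 and for the other genes named in these results, whose loops are not shown to be promoter loops. CEBPA, CEBPB and IRF8, which drive myeloid differentiation, each had 1 loop, at enrichments of 2.27, 2.07 and 1.88. With gene ends within 5 kb of an anchor, the highest value was 10.6 at CEBPB and 3.03 at IRF8. IRF5 had no loop at a gene end. The call for this list of 6 genes was lost in several settings. The odds ratio was 1.60 with wider anchors, 3.92 with a ratio of at least 2 and 4.05 with at least 3 pixels. It stayed at 8.35 against gene sets matched on local gene density, where the call was also lost (permutation adjusted p = 0.112).

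Genes of microglia identity were at an anchor in 19 of 34 cases (55.9%, odds ratio 2.33, interval 1.12 to 4.93, Fisher's exact adjusted p = 0.0422). C1QC, which encodes a chain of complement C1q, had 2 loops, the stronger of 220 kb with 186 contacts and an enrichment of 8.81 (interval 7.59 to 10.2). OLFML3 had 6 loops, the strongest of 305 kb at 5.45, from an anchor that also holds an end of HIPK1, and ITGAX, the integrin CD11c, had 2 up to 4.22. APOE, the apolipoprotein E gene, had 1 loop of 45 kb to the end of CLPTM1, with 223 contacts at 3.92 (interval 3.43 to 4.47). CSF1R, the receptor for the survival factors CSF1 and IL-34, had 1 loop of 160 kb from an anchor shared with HMGXB3 to an anchor with CAMK2A and SLC6A7, with 155 contacts against 72.9 expected, and the fractalkine receptor gene CX3CR1 had 1 loop at 1.84, or up to 5.45 with gene ends within 5 kb of an anchor. The highest value of MERTK, a receptor for the uptake of dying cells, was 17.0 on 17 contacts in a 25 Mb call between anchors that both hold genes with ANAPC symbols; its other 3 loops lay between 2.30 and 2.40. TREM2 and P2RY12 had no loop at a gene end. Against gene sets matched on local gene density the odds ratio stayed at 2.32, with a permutation adjusted p of 0.0596, and with 5 kb anchors alone it was 1.58 (Fisher's exact adjusted p = 0.466).

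Among myeloid regulators, MAF had 8 loops, the strongest of 895 kb at an enrichment of 5.34, and TFEB, a regulator of lysosome genes, had 2 loops, the stronger of 80 kb to FOXP4 with 254 contacts at 6.63 (interval 5.84 to 7.50). BHLHE40 and EGR2 reached 4.80 and 4.76. RUNX1, which is needed for blood cell formation, had 3 loops up to 2.98, and MEF2C had 2 loops up to 3.28. When any part of the gene counted, these values were 5.56 and 5.93. Of 40 genes at Alzheimer's disease risk loci, 22 were at an anchor (55.0%, odds ratio 2.25, interval 1.15 to 4.45, Fisher's exact adjusted p = 0.0320). CLU, the clusterin gene, had 6 loops up to 6.16, APP, the amyloid precursor gene, had 2 up to 4.09 and ECHDC3 had 1 at 4.35. PICALM had 2 loops up to 2.76 and INPP5D 1 at 2.34 (1.52 by the lowest of the 4 ratios), while BIN1 had none at a gene end. With 5 kb anchors alone the odds ratio of the risk list was 1.46 (Fisher's exact adjusted p = 0.497), and against density-matched sets it was 2.21 (permutation adjusted p = 0.0526).

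Pluripotency genes were at an anchor in 15 of 34 cases (44.1%, odds ratio 1.45, interval 0.685 to 3.01), a share not shown to differ from that of other genes (Fisher's exact adjusted p = 0.461). JARID2 had 2 loops, the stronger of 1035 kb at an enrichment of 4.10, MYCN had 5 loops up to 3.76, EPCAM 1 loop at 3.71 and FOXD3 3 loops up to 3.52. SOX2 had 2 loops of 425 and 800 kb, both at 2.24, and SALL4, LIN28A and LIN28B had 1 loop each at 2.56, 2.38 and 1.96. With gene ends within 5 kb of an anchor, the highest value was 5.86 at SOX2 and 5.20 at LIN28B. POU5F1, NANOG and DNMT3B had no loop at a gene end. The cassette, microglia and myeloid lists together had 48 of 75 genes at an anchor (64.0%). Against the pluripotency list this gave an odds ratio of 2.25 (interval 0.911 to 5.59, Fisher's exact p = 0.0615, adjusted p = 0.123 over 6 comparisons of lists), so a difference between these lists was not shown. Pluripotency genes were at anchors less often than developmental transcription factors (odds ratio 0.172, Fisher's exact adjusted p = 0.00113), and the combined myeloid lists were not shown to differ from them (odds ratio 0.388, Fisher's exact adjusted p = 0.0697).

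Genes of the responses to LPS and to IFNG did not pass the test. Of 45 genes of the LPS and NF-kB response, 16 were at an anchor (35.6%, odds ratio 1.01, interval 0.513 to 1.93, Fisher's exact adjusted p = 1), and of 54 IFNG response genes, 26 were (48.1%, odds ratio 1.71, interval 0.960 to 3.02, adjusted p = 0.119). The IFNG list had a permutation adjusted p of 0.00599 when set against random loop placements, a setting that raises the odds ratio of every list, that of the LPS list to 1.58, because loops carry more gene ends than placed loops. The 2 lists were not shown to differ from each other by Fisher's exact test (odds ratio 1.68, interval 0.695 to 4.11, p = 0.227). CCL3, a chemokine gene, had a loop of 50 kb at 6.92, a single pixel with 64 contacts against 9.25 expected. The median expected count of loops up to 0.1 Mb was 36.3. TNFAIP3, which encodes the NF-kB inhibitor A20, had 2 loops with the stronger at 5.12 (interval 4.39 to 5.93), and IL6 had 3 loops up to 4.92. PTGS2 reached 3.57, NFKBIA 2.97 (1.87 by the lowest of the 4 ratios), CCL2 2.63, in a loop to CCL1, and IL1B 2.20. Among IFNG response genes, SOCS1 and SOCS3, which restrain cytokine signalling, reached 4.64 and 4.43, HLA-DRB1 reached 4.50 in a loop to HLA-DRB5, a close paralog, and HLA-DMA reached 4.38. IRF1, a transcription factor of the IFNG response, had 2 loops up to 2.56. TNF, CXCL10 and CIITA had no loop at a gene end.

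Developmental transcription factors also had the stronger loops. Their 139 loops had a median enrichment of 3.43, against 2.70 for the other loops with a gene end (difference 0.734, permutation adjusted p = 4.20e-04, from the smallest p the resamples can give). HOX genes, which pattern the body axis, were at an anchor in 30 of 39 cases (odds ratio 6.14, Fisher's exact adjusted p = 1.20e-06), and their 42 loops had a median of 3.43 against 2.70 (difference 0.723, permutation adjusted p = 0.00588). The other 19 of the 21 lists did not pass the enrichment test, and 4 of the 21 had an unadjusted p under 0.05. With wider anchors alone, histone loops (difference 0.672, permutation adjusted p = 0.00627) and lymphocyte loops (0.963, permutation adjusted p = 0.0389) passed. With a ratio of at least 2, fibroblast and endothelial loops passed with a lower median (-0.533, permutation adjusted p = 0.0335). PAX3 reached 14.9 in a loop of 3315 kb to FEV, and ISL1 reached 14.7 in a loop of 3840 kb to MCIDAS, on 14 and 13 contacts. PAX8 and EN1 were joined by a call of 5.57 Mb at 12.7 on 20 contacts (interval 7.75 to 19.6). HOXA4, HOXA5 and HOXA6 shared an anchor in a 25.9 Mb call to UNCX at 12.4, on 25 contacts against 2.02 expected. HOXC11 was in a 60.7 Mb call to TBX3 at 12.2, on 23 contacts against 1.89 expected. For these calls over 5 Mb, a mapping effect or a rearrangement was not tested. The HOX genes lie in 4 clusters, too few for the test to decide when neighbours are counted once. In that setting the odds ratio was 5.93 and the list did not pass (Fisher's exact adjusted p = 0.283). Its odds ratio was 3.06 with 5 kb anchors alone, 3.43 when any part of the gene counted, 10.4 against random placements and 17.6 with gene ends within 5 kb of an anchor. The difference for developmental factors was 0.383 with 5 kb anchors alone (permutation adjusted p = 0.330) and 0.385 among loops of at least 3 pixels (permutation adjusted p = 0.475). Within strata of anchor width and length, the developmental factors passed with a difference of 0.366 and the HOX genes did not (0.360, permutation adjusted p = 0.275). The HOX call was also lost with the lowest of the 4 ratios (0.220), with 5 kb anchors alone (0.928), with gene ends within 5 kb (0.594) and when any part of the gene counted (0.538).

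Clustered gene families went both ways. Of 390 olfactory receptor genes, 46 were at an anchor (11.8%, odds ratio 0.240, interval 0.172 to 0.328, Fisher's exact adjusted p = 6.26e-25), and of 53 clustered protocadherin genes, 7 were (odds ratio 0.278, adjusted p = 0.00158). With neighbours counted once, the olfactory receptors formed 49 loci and still passed, at an odds ratio of 0.338 (Fisher's exact adjusted p = 0.0300). Zinc finger genes with ZNF symbols had 148 of 509 at an anchor (odds ratio 0.747, Fisher's exact adjusted p = 0.00912). Histone genes had 42 of 73 at an anchor (odds ratio 2.49, Fisher's exact adjusted p = 4.80e-04), and 16 of their 29 loops had histone genes at both anchors. H2AC4 on chromosome 6 was joined to H2AC11, H2BC11 and H2BC12 by a loop of 1100 kb at 6.52 (interval 4.75 to 8.72). Outside the MHC interval, which holds most histone genes, the odds ratio of this list was 0.109 and passed in the opposite direction (Fisher's exact adjusted p = 0.0179), and the call was lost with neighbours counted once (1.18) and when any part of the gene counted (1.20). The protocadherin odds ratio was 1.87 when any part of the gene counted. The call was lost with 5 kb anchors alone (0.666), with at least 3 pixels (0.421) and against random placements (0.450). With neighbours counted once (0.250) the list is 1 locus, which cannot pass the test whatever the data. The ZNF call was lost with wider anchors (0.930), against density-matched sets (0.827), against random placements (1.02) and with neighbours counted once (1.18). OR2T2 and OR2T27 were joined over 210 kb on 17 contacts against 1.42 expected. ZNF488 reached 74.9 in a loop of 1100 kb, on 139 contacts against 1.85 expected. The median expected count was 22.1 for loops of 0.2 to 0.5 Mb and 19.9 for those of 1 to 2 Mb. These 2 ratios therefore rest on unusually low expected counts, and a mapping effect was not tested.

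Genes of other cell types and of basic functions were not shown to differ from other genes. By Fisher's exact test the adjusted p was 0.673 for neuron genes (10 of 23), 0.901 for astrocyte and oligodendrocyte genes (6 of 19), 0.667 for fibroblast and endothelial genes (8 of 18), 1 for lymphocyte genes (8 of 24), 0.754 for hepatocyte genes (8 of 20), 0.680 for genes of other neurodegenerative diseases (11 of 27), 0.236 for genes of loop architecture (9 of 17) and 0.667 for ribosomal protein genes (24 of 77). When any part of the gene counted, the ribosomal list passed with an odds ratio of 0.423 (Fisher's exact adjusted p = 0.00140). Microglia identity genes were not shown to differ from neuron genes (Fisher's exact p = 0.424) or from lymphocyte genes (p = 0.113). CAMK2A had 5 loops up to 5.02 and GAD1 7 loops up to 4.87. CD8A and CD8B shared a 25.5 Mb call at 23.2, on 42 contacts against 1.81 expected. The MERTK call with ANAPC symbols at both anchors also holds an end of CD8B. MAPT, the tau gene, shared an anchor with KANSL1 in an 18.9 Mb call to LRRC37A3 at 65.1, on 39 contacts against 0.599 expected. For calls as long as these, a mapping effect or a rearrangement was not tested. TARDBP had a loop to FBXO2 at 4.17. Of the cohesin-associated genes, PDS5B reached 7.01, ESCO1 5.95, PDS5A 5.39 and STAG1 5.10, while CTCF, whose protein marks loop anchors, had no loop at a gene end. The cell type lists can only be read as lists in a pool, since no loop is assigned to stem cells or microglia.

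Some regions took part in many loops. Overlapping anchors merged into 28826 regions, of which 12331 (42.8%) were in at least 2 loops and 1355 (4.70%) in at least 5. The highest number depends on the loops used, 6 with 5 kb anchors alone and 7 with at least 3 pixels. The region with the most, 12 loops, lay on chromosome 6 at 139350001 to 139380000 and held the end of CITED2, a transcriptional coregulator, whose strongest loop was 1550 kb long at 7.95. The next highest number was 11 loops, shared by a region of chromosome 2 with SP9 and CIRSR, a region of chromosome 5 with MED7 and regions with no protein-coding gene end. Counting only loops whose own anchor held the gene end, CITED2, SP9 and CIRSR had 6 each and MED7 had 4. By that count MYC, on chromosome 8, was in 9 loops, all reaching to the same side. Its longest spanned 1945 kb and was also its strongest, at 5.39 (interval 3.96 to 7.17); with wider anchors alone the highest was 3.08. Of the 34 key genes, 23 had an end in an anchor and 11 did not. A gene without a called loop may still have contacts below the caller's threshold, and loops that differ between stem cells and microglia can be diluted in a pooled list.

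Calls over 5 Mb included the extreme values of the list. The highest ratio, 3606, joined regions of chromosome 12 that lie 99.5 Mb apart, with 25 observed contacts against 0.00693 expected. ALG1L2 on chromosome 3 had 3 calls over 54 Mb long with ratios from 510 to 811. The longest call, 223 Mb on chromosome 1, had 51 contacts against 0.0669 expected. The 4 next longest joined a region of chromosome 1 at 234775001 to 234800000 to a stretch near the other end with DNAJC16, SPEN and EPHA2, with ratios from 24.3 to 73.7. That window held 10 such calls, with partners between 15525001 and 17575000. Most of them had expected counts under 1, where the ratio rests on the caller's estimate of the background, but the call with the most contacts, between 16720001 and 234790000, had 368 against 33.5 expected. A rearrangement of the line or a mapping effect, which would change what these lengths and ratios mean, was not tested.

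**Figure D3:**
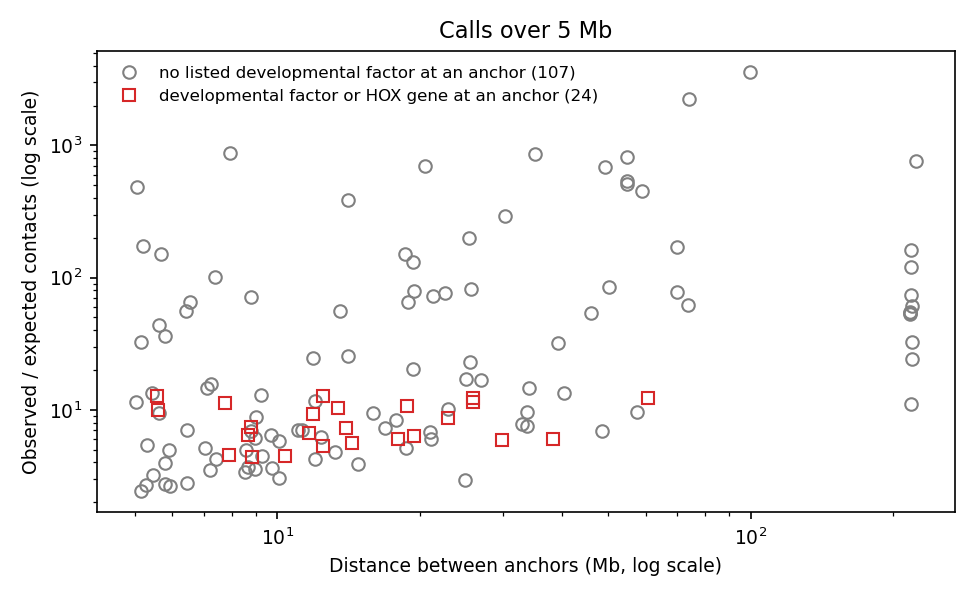
The 131 calls over 5 Mb by distance between their anchors in Mb and by observed over expected contacts, both on log scales; red squares are the 24 calls with a gene of the fixed developmental factor or HOX lists at an anchor and grey circles the other 107, which include developmental factors outside those lists. The median ratio was 7.35 for the squares and 15.7 for the circles, and the highest was 3606.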

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

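No paired analysis was possible because the loop list has no values per library, so fits with and without a replicate block, with other size factors or without each replicate were not run. The settings that need gene strand, transcripts or the genome sequence (5' ends of all transcripts and the CTCF motif settings) were not run either. Genes with any part in an anchor, loops of at most 5 Mb and list members within 500 kb counted once were chosen after seeing the data. The excess of gene ends over placement, the positive rank correlation of enrichment with length, and the odds ratios of developmental transcription factors and myeloid regulators kept their direction and their side of the threshold in every setting run for them. Leaving aside the named genes' ratios, 217 of the values of the main comparisons stayed, 24 moved, 21 lost the threshold and 1 gained it. Of the lists, these counts cover only the cassette, microglia, myeloid, pluripotency, LPS, IFNG, Alzheimer's disease and developmental factor lists. Among the remaining values, which include those of the other lists, 270 stayed, 14 lost the threshold, 4 gained it and 4 reversed direction. The 21 leave out the settings in which the cassette factors have no finite odds ratio, where the threshold was lost too. Of the named genes' highest ratios, 191 stayed within the counting interval and 30 moved. Settings that left a gene with no loop are not in these counts, such as wider anchors for SPI1 and 5 kb anchors for CSF1R. A median of 76 observed contacts limits single loops, and where the cause of a change is not given by the construction of the setting, the cause was not tested.

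By construction, 5 kb anchors alone left 15005 loops (median length 200 kb, enrichment 3.42), wider anchors alone 11286 (500 kb, 2.46) and loops of at least 3 pixels 12926 (232.5 kb, 3.32). The median enrichment was 2.96 with a ratio of at least 2 and 2.22 with the lowest of the 4 ratios. The highest number of loops per region was 6 with 5 kb anchors and 7 with at least 3 pixels. The number of lists called at anchors, 10, was 6 with wider anchors, 6 against density-matched sets, 6 with any part of the gene and 3 with neighbours counted once. In the last setting the HOX list has 4 loci and the protocadherin list 1, too few for the test to decide. The number of lists called for loop enrichment, 2, was 0 with 5 kb anchors, 4 with wider anchors, and 1 each with at least 3 pixels, the lowest of the 4 ratios, gene ends within 5 kb, strata of width and length, and any part of the gene.

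The odds ratio of the cassette factors lost the threshold at 9.07 on chromosomes 1 to 22, 8.35 against density-matched sets, 9.18 with neighbours counted once, 4.05 with at least 3 pixels, 1.60 with wider anchors and 3.92 with a ratio of at least 2, and also with gene ends within 5 kb and with any part of the gene, where all 6 genes were at an anchor and no finite odds ratio exists. That of microglia identity genes lost it at 1.26 with any part of the gene, 2.32 against density-matched sets, 1.74 with gene ends within 5 kb, 1.99 with neighbours counted once, 1.98 with wider anchors, 1.58 with 5 kb anchors and 1.96 with a ratio of at least 2. That of Alzheimer's disease risk genes lost it at 2.06 with any part of the gene, 2.21 against density-matched sets, 1.59 with gene ends within 5 kb, 2.17 with neighbours counted once, 2.132 with wider anchors and 1.46 with 5 kb anchors. That of IFNG response genes gained it at 2.59 against random placements, where by construction no list has a no-change value of 1. The enrichment difference of developmental factors lost it at 0.383 with 5 kb anchors and 0.385 with at least 3 pixels. Among the lists that passed, odds ratios crossed 1 for protocadherins (1.87, any part of the gene), ZNF genes (1.18 with neighbours counted once, 1.02 against random placements) and histone genes (0.109 outside the MHC, where the setting removes most of them).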

Other observations

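The tests of sequence shared by both anchors, of pairing among developmental factors, of chance calls and of the difference between myeloid and pluripotency genes were chosen after the results were seen; the tests of gene density, anchor width and local loop number were written beforehand. Developmental factor and HOX genes also met each other in loops. There were 13 calls with genes of these fixed lists at both anchors, a number that leaves out factors not listed. IRX3 and IRX5 were joined over 0.645 Mb with 100 contacts at an enrichment of 6.38 (95% interval 5.19 to 7.76), VAX1 and EMX2 over 0.41 Mb at 8.53 on 33 contacts, and PAX9 and FOXA1 over 0.93 Mb at 5.48. LHX5 and TBX3 were joined over 1.21 Mb at 5.72, and DLX1 and DLX2 met HOXD genes over 4.03 Mb at 7.19 (interval 5.27 to 9.59). Most of these genes were chosen after their values were seen. The share of calls with such a gene was 0.324% up to 0.1 Mb, 1.74% between 1 and 2 Mb and 18.3% over 5 Mb.

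Calls over 5 Mb form the first pattern. HAND1 was joined to NKX2-5 over 18.8 Mb at 10.8 on 20 contacts, names chosen after their values were seen. Chance calls at low expected counts stay open: the 24 calls with such a gene make up 18.3% of the 131 (exact binomial interval 12.1 to 26.0%) against 1.65% of calls of 1 to 5 Mb at the same anchor widths, but this share is the observation that drew attention to them and not a separate test. A preferred pairing of these genes is a candidate explanation. Over 5 Mb, 6 calls had a listed gene at both anchors, against a mean of 2.65 in 10000 re-pairings within chromosomes (one-sided permutation p = 0.0145). Over 2 Mb, the length tried first, there were 7 against 1.06. These 7 include the same 6 calls, so they are not separate support. The 6 calls are not all independent, and 79.2% of the 24 rest on a single pixel. Sequence shared by both anchors stays open in both parts. The test looked for genes of one symbol family at both anchors, a coarse stand-in for alignment. Only calls with named genes at both anchors could score, 46 of the other 107 calls and 19 of the 24. The 107 include developmental factors outside the lists. One family lay at both anchors in 11 of the 107 (10.3%). Re-pairings within chromosomes had a median of 4 and a highest value of 12 (permutation p = 8.00e-04). Re-pairing across chromosomes, run first and replaced as too lenient, gave at most 4 and would have fitted. Among the 24 calls the share was 0% (interval up to 14.2%).

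The frequent place of developmental factor genes at anchors is the second pattern. Local gene density is argued against as its whole cause by an odds ratio of 6.60 against density-matched sets (permutation p = 2.00e-05, the smallest they can give), and wide anchors by 3.80 with 5 kb anchors alone. A region rich in loops is argued against too, since 55 genes at an anchor were 4.37 times the number expected from the share of the surrounding 1 Mb that anchors cover. All protein-coding genes reached 1.52 times by that measure, so a scaling to all genes was added after this was seen, with which the excess was 2.80 (exact p = 1.21e-20). Which cells give these loops was not tested, as the list is pooled.

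The third pattern is the place of the cassette, microglia and myeloid genes at anchors. Their joint odds ratio was 3.13 against density-matched sets (permutation p = 2.00e-05), which argues against local gene density as the whole cause for the joint set. Taken singly, only the myeloid regulators passed there (3.73, permutation adjusted p = 0.00160). The cassette factors (8.35, permutation adjusted p = 0.112) and the microglia identity genes (2.32, permutation adjusted p = 0.0596) did not. With 5 kb anchors alone the odds ratios were 2.60, 8.78 and 1.58, and only the microglia identity list lost its call. The 48 genes at an anchor were 2.71 times the number expected from local anchor cover, and 1.79 times when scaled to all protein-coding genes (exact p = 3.17e-07). A larger part of the contacts coming from microglia than from stem cells may raise these lists, but the difference from pluripotency genes had a Fisher's exact p of 0.0615 and the libraries behind the list are not stated, so this cannot be told apart from a property of the genes themselves.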
